A study of Mus musculus with 6 samples.

How the data were processed

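Poly(A) or total RNA selection is not given in the sources used here; the labels describe total RNA from mouse liver made into libraries by a standard Illumina protocol. The 6 libraries came from male C57BL/6 mice, an inbred laboratory strain, that were 6 weeks old when dosing began. Per the labels, 3 libraries belong to mice given polystyrene microplastics (PS-MP, small particles of the plastic used in packaging foam) by mouth at 0.4 mg per day, with 2 dosings a week for 8 weeks, and 3 belong to mice given water on the same schedule. Groups and replicate numbers were taken from the labels. No label gives a batch, a cage, an hour of collection or a feeding state. No label says in words that the 3 libraries of a group came from separate mice, so p-values measure the spread between these libraries.

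The deposited files hold 1 FPKM value per gene and library, a read number scaled by exon length and by library total, made by the authors. Per the submitters' processing notes, base calling used CASAVA, read quality was examined with FastQC and MultiQC, reads were trimmed with Trimmomatic 0.38, aligned with HISAT2 2.1.0 and counted per gene with featureCounts 1.6.0, and DESeq2 1.22.1 is also named there. The same notes name the human build GRCh38, whereas all 55536 gene identifiers in the files are those of the mouse annotation GENCODE M21 on GRCm38, which holds 55536 genes. Gene symbols and coordinates below come from GENCODE M21 on GRCm38. Whether the counting used strand, and whether it counted reads or read pairs, is not given in the sources used here, so "reads" below stands for whichever was counted, and a gene that overlaps another cannot be separated from it with certainty.

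The FPKM values were checked for the reads behind them. Each value times the summed length of the gene's merged exons, divided by the step of its library, was a whole number within 0.001 reads for 100.0% of the genes above 0 in each library, and the largest distance from a whole number was 0.00013 reads. The library total that the step implies was equal to the sum of the recovered reads in all 6 libraries. The totals ran from 13082210 to 16948343 reads. They give the depth, the low-count rule and CPM (reads scaled to a common library total); intervals from reads cover counting error only.

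The design had been fixed for counts before the data were examined, with a fallback for normalized values. Since the deposited unit is FPKM, the fallback was used: limma-trend (limma 3.58.1 in R 4.3.3; empirical Bayes with a mean-variance trend) on log2(FPKM + 0.5), with the group as the only term, all 6 libraries in the fit, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. A fold change is on the scale of FPKM + 0.5 and so understates the change of genes with low values. The scaling is that of the deposited values, by library total. Genes were tested when they had at least 0.66 CPM (10 reads in a library of median size) in at least 3 libraries and at least 15 reads in all, which left 13299 genes.

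Before the data were examined, 41 lists of pathway genes and cell type markers were written from general knowledge of liver. Of these, 39 had at least 3 tested members and were tested with camera, which compares a list with all other tested genes, at a preset correlation between genes of 0.01. The same lists were tested with a correlation estimated from the data and with fry, which asks whether the genes of a list move on balance in 1 direction. Named genes follow a rule written at the same time: the 12 higher and 12 lower genes with the smallest p among changed genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted gene models; up to 4 members with the smallest p in each list past its threshold and up to 2 in each other list; up to 4 changed members of any list; and the members of any count of 5 or fewer. Some genes that meet the rule are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. A further 5 lists, of brain, peripheral nerve and fat transcripts, were written after the data had been seen.

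The procedure was tested on simulated data drawn from the means and totals of these libraries, in 5 runs with 200 changed genes each, a dispersion of 0.04 and 13479 genes tested on average. In the simulated comparison of PS-MP with water, limma-trend called 5.2% of the genes changed by 1.5 times. It called 37.1% of those changed by 2 times and 93.4% of those changed by 4 times, and 6.9% of its calls were false. Limma-voom, run on the simulated reads, called 9.6%, 50% and 94.8% of these genes, and 4.1% of its calls were false. With the lists, camera called 10 of 10 lists moved by 1.5 times and 0 of 186 unmoved ones, in simulated data whose genes vary independently. Within each group, no pair of libraries held identical values, and the chi-square of their reads over the genes with at least 20 reads was 9.99 to 28.26 times its degrees of freedom, so no library was a copy of another.

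Alternatives were other scalings, pseudocounts, low-count rules, thresholds, limma-voom on the recovered reads, the replicate number as a block, the 20 most abundant genes left out, each library left out in turn and the libraries with brown fat transcripts left out together. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used to read the files and to plot. Histology, which the study also examined, is not analysed here.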

Results

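The comparison asked which liver transcripts differ between mice dosed by mouth with polystyrene microplastics (PS-MP) for 8 weeks and mice given water. RNA sequencing of liver gave 6 libraries, 3 per group. Recovered totals were 15186243, 16948343 and 14520402 reads in water replicates 1, 2 and 3, and 13082210, 15938284 and 14918658 reads in PS-MP replicates 1, 2 and 3. Genes with at least 1 read numbered 20313 to 20384 in the water libraries, 20468 and 20719 in PS-MP replicates 1 and 2, and 21836 in PS-MP replicate 3. Albumin took 5.77% to 7.95% of the reads of a library, and the mRNAs encoded by mitochondrial DNA took 8.48% to 9.49%.

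Transcripts of other tissues were unevenly spread over the libraries. Snap25, a protein of nerve terminals, had 1, 2 and 0 reads in the water libraries and 61, 19 and 860 reads in PS-MP replicates 1, 2 and 3. Camk2a, a kinase abundant in forebrain neurons, had 1, 3 and 0 reads against 58, 19 and 670 reads. Ucp1, the uncoupling protein of brown fat, had 139, 0 and 15 reads in water and 0, 0 and 68 reads in PS-MP. These genes, and those plotted with them, were chosen after their values were seen. On log-scale expression the first principal component took 35.1% of the variance and set PS-MP replicate 3 (44.00) apart from the other 5 libraries, which lay between -21.62 and 9.39.

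**Figure D1:**
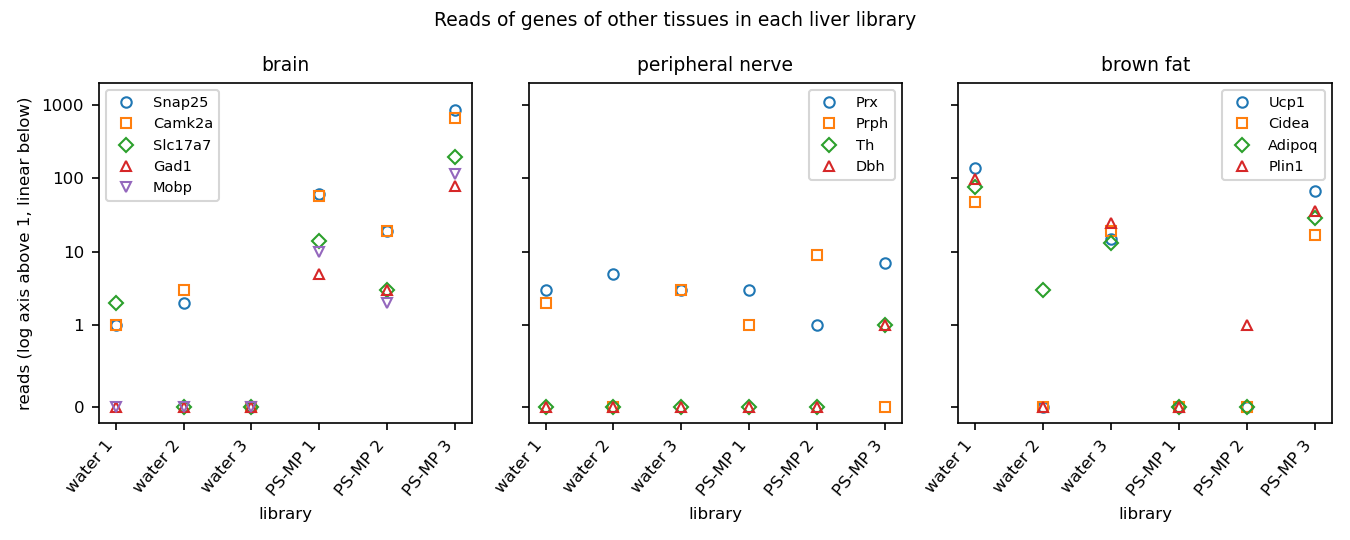
Reads (vertical axis, logarithmic above 1 and linear below) of genes known from brain, peripheral nerve and brown fat in each of the 6 liver libraries (horizontal axis); each symbol is 1 gene in 1 library. Snap25 reaches 860 reads in PS-MP replicate 3 and at most 2 in water, Prx of peripheral nerve stays at 1 to 7 reads, and Ucp1 has 139 reads in water replicate 1 and 68 in PS-MP replicate 3.

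Alas1, Cyp2a5 and Per3 were among the genes higher in PS-MP, and Cdkn1a and Chka among the genes lower in PS-MP. With limma-trend, 65 of 13299 genes changed at an adjusted p under 0.05, of which 32 were higher and 33 lower in PS-MP. Of the 65, 25 changed at least 2 times (14 higher and 11 lower), and 12 are predicted gene models. In all 65 the 3 PS-MP values lay outside the range of the 3 water values; over all genes tested this held for 19.2%, where chance gives 10%. Unadjusted p was under 0.05 for 1737 genes, where chance gives 665. For any of these genes, an effect of PS-MP cannot be told apart from a group difference in collection hour or feeding. No label gives either.

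The count rested on each of several libraries. Without water replicate 1, 2 or 3 the number of changed genes was 3, 31 or 0, and without PS-MP replicate 1, 2 or 3 it was 36, 2 or 13 (the 3 were Cyp2a5, Alas1 and Cdkn1a, and the 2 were Cyp2a5 and Alas1), while 1641 genes had an unadjusted p under 0.05 in the limma-trend fit that called 0. All 65 genes kept their direction in each of these fits. This was fixed in advance, because their PS-MP values all lie on 1 side of their water values. With no low-count rule, which raised the genes tested to 26854, limma-trend called 0 genes and 2064 had an unadjusted p under 0.05. With the low-count rule kept, limma-voom on the recovered reads called 131 of 13299 genes, 58 of them among the 65.

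Among the higher genes, Alas1, the first and rate-limiting enzyme of haem synthesis (chromosome 9, 106233455 to 106248654), went from 33.9 ± 3.59 FPKM in water to 114.5 ± 18.5 in PS-MP (SD, n = 3 each), a 3.32-fold change with a log2 standard error of 0.13 and an adjusted p of 0.00831. Cyp2a5, a cytochrome P450 that oxidises coumarin and nicotine (chromosome 7, 26835305 to 26843548), went from 96.7 ± 14.7 to 278.0 ± 14.7 FPKM (SD, n = 3 each; 2.88-fold, log2 standard error 0.11, adjusted p = 0.00831 by limma). Its near-identical neighbour Cyp2a4 was 2.02-fold higher at 0.49 FPKM in water, and reads could be split between the 2 copies, so both values are uncertain. Por, which passes electrons to all microsomal P450 enzymes, was 1.51-fold higher. Upp2, a uridine phosphorylase of liver, was 3.38-fold higher, Slc7a2, a transporter of arginine and lysine, 1.72-fold, and Id1, a target of BMP signalling, 2.49-fold. Mtss1 (2.15-fold), Mir22hg (1.52-fold), Zfp445 (1.68-fold) and Jph1 (1.70-fold, from 0.20 FPKM in water) were also higher.

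Among the lower genes, Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), went from 11.97 ± 1.44 to 4.31 ± 0.51 FPKM (SD, n = 3 each; log2 fold change -1.37, standard error 0.12, adjusted p = 0.0093 by limma). Clpx, part of a mitochondrial protease that acts on the ALAS1 protein, had a log2 fold change of -1.26. Chka, the first enzyme of phosphatidylcholine synthesis from choline, had -0.93, and Cldn1, a tight junction protein, had -0.86. Slc34a2, a sodium-dependent phosphate transporter, had -1.09 at 0.74 FPKM in water. Spon2 (-1.33), Ackr2 (-1.001), Mreg (-0.73), Pxmp4 (-0.65), Efna1 (-0.59) and Caprin1 (-0.47) were also lower. Of the 24 higher and lower genes with the smallest p, 5 (Slc7a2, Per3, Mir22hg, Zfp445 and Por) overlap another tested gene.

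**Figure D2:**
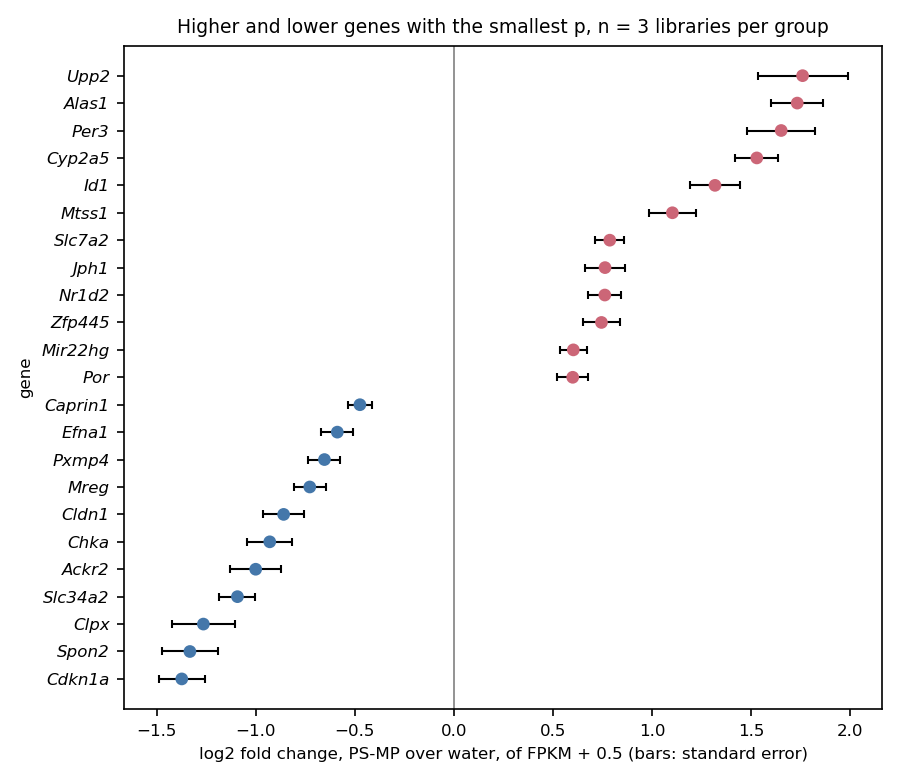
Log2 fold change of PS-MP over water, on the scale of FPKM + 0.5 (horizontal axis), for the higher and lower genes with the smallest p that are named here (vertical axis); points are limma estimates from 3 libraries per group and bars are standard errors. The values run from -1.37 for Cdkn1a to 1.76 for Upp2.

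Circadian genes that peak with the PER genes were higher in PS-MP as a list with camera (adjusted p = 8.96e-15, and adjusted p = 0.598 with an estimated correlation). Of 14 tested, 13 had a positive fold change, 4 passed the test over all genes and 13 passed when adjusted over the list alone. Dbp, a transcription factor that follows the clock and drives detoxification genes, went from 1.99 ± 1.16 to 12.6 ± 3.98 FPKM (SD, n = 3 each; log2 fold change 2.45, standard error 0.33, adjusted p = 0.0366 by limma); it overlaps Sphk2 on the other strand. The related factor Tef had a log2 fold change of 1.04, Per3 of 1.65 and the clock repressor Nr1d2 of 0.76, and all 3 changed. Ciart (2.65), Usp2 (2.28) and Per2 (0.75) did not pass over all genes, with adjusted p of 0.0567, 0.0616 and 0.143. Nr1d1 was the exception, at 22.6 ± 3.65 FPKM in water and 21.1 ± 2.26 in PS-MP (SD, n = 3 each). Ciart, Usp2, Per2 and Nr1d1 were chosen after their values were seen. Circadian genes of the opposite, BMAL1 phase were lower as a list with camera (adjusted p = 0.00441, and adjusted p = 0.598 with an estimated correlation), and 5 of 6 had a negative fold change. Arntl, which encodes BMAL1, changed by -1.23, and Npas2 (-0.99) and Nfil3 (-0.92) passed when adjusted over the list alone.

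The median log2 fold change was 0.76 over the PER-phase list and -0.55 over the BMAL1-phase list (-0.17 with no low-count rule). PS-MP replicate 3, with the most Snap25 reads, had the highest Dbp value (17.1 FPKM against 9.60 and 11.1 in PS-MP replicates 1 and 2, and at most 3.29 in water); without that library the medians of the lists were 0.69 and -0.47.

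**Figure D3:**
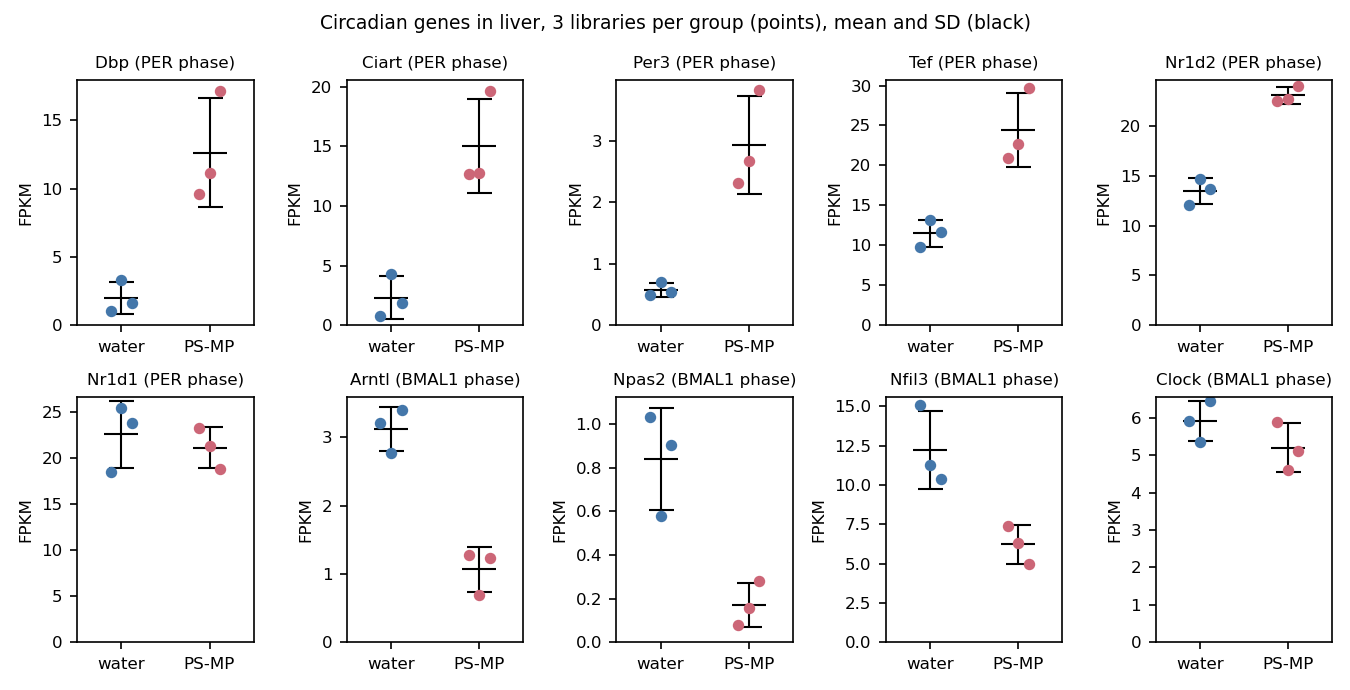
FPKM (vertical axes, each from 0) of 10 circadian genes in the water and PS-MP libraries (horizontal axis); each point is 1 library, with the mean and SD of 3 libraries in black. Dbp was 1.06 to 3.29 in water and 9.60 to 17.1 in PS-MP, Arntl was 2.78 to 3.40 in water and 0.69 to 1.28 in PS-MP, and the values of Nr1d1 overlap between the groups.

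Genes of fatty acid oxidation and targets of PPARalpha, the receptor that turns them on in fasting, were lower as a list with camera, with a median log2 fold change of -0.26 (adjusted p = 3.78e-09, and adjusted p = 0.598 with an estimated correlation). Of 30 tested genes, 27 had a negative fold change, 0 passed the limma-trend test over all genes (12 had an unadjusted p under 0.05), and 3 passed when adjusted over the list alone: Fgf21, a fasting hormone (log2 fold change -1.30), the thioesterase Acot2 (-1.30) and the lipase inhibitor Angptl4 (-0.41). Acot1, a close copy of Acot2, had -0.97 and did not pass. Ppara itself, chosen after its values were seen, was at 47.2 ± 3.96 FPKM in water and 48.7 ± 3.37 in PS-MP (SD, n = 3 each). Without PS-MP replicate 3, the library with the most brain transcripts, the median was -0.14 and the camera adjusted p was 2.21e-06. The labels give no feeding state, so a difference in feeding between the groups cannot be told apart from PS-MP here.

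Among the other lists past camera's threshold, periportal hepatocyte genes, which mark the zone of urea and glucose production, were higher with a median log2 fold change of 0.22 (16 of 18 positive, 0 changed over all genes or adjusted over the list alone, adjusted p = 0.00389, and adjusted p = 0.606 with an estimated correlation). The call was lost with the 3 libraries that hold brown fat transcripts left out, a fit that leaves a lone water library (median 0.07). Over all its alternatives, the periportal list had a camera adjusted p from 1.42e-05 to 0.606. Its members with the smallest p were Sds (0.66), Hal (0.22), Aldh1b1 (0.44) and Ass1 (0.39). Interferon-stimulated genes were lower with a median of -0.03 (28 of 38 negative, 0 changed over all genes, adjusted p = 0.0094, and adjusted p = 0.598 with an estimated correlation). Igtp (-0.46), Irf9 (-0.38), Irgm2 (-0.33) and Isg15 (-0.71) passed when adjusted over that list alone, and Igtp and Irgm2 overlap each other. Without PS-MP replicate 1 the interferon list's camera adjusted p was 0.0642. Its call was also lost with the 3 libraries that hold brown fat transcripts left out (median -0.05). The median ran from -0.01 without water replicate 1 to -0.11 without PS-MP replicate 3. Cytosolic ribosomal protein genes were lower with a median of -0.05 (38 of 47 negative, none of which changed, adjusted p = 0.0336, and adjusted p = 0.899 with an estimated correlation), and Rpl32 (-0.20) had the smallest p. B and plasma cell markers were lower with a median of -0.16 (7 of 9 negative, adjusted p = 0.0386, and adjusted p = 0.598 with an estimated correlation), with Ighd at -0.39 and Igkc at -0.44. The B and plasma cell list lost its call without water replicate 3 (adjusted p = 0.0919) and without PS-MP replicate 2 (0.175), and the ribosomal list without water replicate 1, PS-MP replicate 1 or PS-MP replicate 3. The B and plasma cell list also lost it with median-of-ratios or TMM scaling and with CPM of at least 1 in 3 libraries. So it did with limma-voom or the 20 most abundant genes left out (camera adjusted p from 0.0511 to 0.0985 over these settings). That list lost it as well with the 3 libraries that hold brown fat transcripts left out (median -0.22). Its median ran from -0.40 with limma-voom to -0.09 with a pseudocount of 1.

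With an estimated correlation 0 of 39 lists passed (2 had an unadjusted p under 0.05), and with fry 0 passed (6 had an unadjusted p under 0.05). Targets of the xenobiotic receptors CAR, PXR and AhR did not pass as a list (median 0.05, adjusted p = 0.236). Adjusted over that list alone, 6 of its genes were higher and 1 lower. Of its 22 tested genes, 2 changed, both higher (Cyp2a5 and Por), and Cyp2b10 and Cyp3a13, chosen after their values were seen, had log2 fold changes of -1.18 and 0.33, with adjusted p of 0.107 and 0.103. Fatty acid and triglyceride synthesis did not pass (adjusted p = 0.359), though Elovl5, which lengthens polyunsaturated fatty acids, was lower (-0.62). In the list of the unfolded protein and integrated stress responses (adjusted p = 0.93) 1 gene changed, Atf5 (-0.54), and in that of p53 targets and DNA damage (adjusted p = 0.281) Cdkn1a did, while Gadd45a had 0.71 and an adjusted p of 0.0925.

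The following lists gave no call. NRF2 and antioxidant genes had a median log2 fold change of -0.02 (0 of 26 changed, adjusted p = 0.446), with Srxn1 at -0.41 and Nqo1 at 0.32. NF-kB targets, cytokines and chemokines had a median of -0.11 (0 of 17 tested genes changed, adjusted p = 0.186). That list holds 26 genes, and the low-count rule left Tnf, Il6, Ccl2, Ccl3, Ccl4, Ccl7, Ccl22, Cxcl2 and Ptgs2 untested. The median was 0.07 for inflammasome genes (adjusted p = 0.578) and 0.08 for acute phase proteins (adjusted p = 0.106). Ferroptosis and iron genes had 0.00, with a mean of 0.11 (adjusted p = 0.547), and stellate cell, fibroblast and matrix genes -0.06 (0 of 30 changed, adjusted p = 0.133). Kupffer cell and macrophage markers had a median of 0.10 (17 of 21 positive, adjusted p = 0.106), sinusoidal endothelial markers -0.05 (adjusted p = 0.446), cholangiocyte markers -0.04 (adjusted p = 0.214) and hepatocyte genes -0.03, with a mean of 0.02 (adjusted p = 0.771). Adipose markers had a median of -0.61 over 6 genes (adjusted p = 0.259), with Cfd at -1.88 ± 1.23 (standard error). The remaining lists had adjusted p from 0.0912, for heat shock proteins (median -0.10), to 0.975, for the cell cycle and for antigen presentation; in these, Plin2 of lipid droplets had -0.73 (adjusted p = 0.0627) and Cyp8b1 of bile acid synthesis -0.76 (adjusted p = 0.0873), and 1 gene changed, Cyp2a4 in the list of female-biased genes. Neutrophil and exocrine pancreas markers had 2 and 1 tested members and were not tested as lists. In the simulated data, limma-trend called 5.2% of the genes changed by 1.5 times and 37.1% of those changed by 2 times. The real genes need not vary as simulated. The 65 changed genes had a median absolute log2 fold change of 0.76 and a smallest of 0.45. Changes in the lists without a call can have been missed.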

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

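The tests of the brain transcripts below, and the genes named with them, were chosen after their reads had been seen. Of the 18 forebrain neuron and the 14 oligodendrocyte and astrocyte transcripts listed, 2 in each list are at 1 FPKM or more in every water library. A further 13 fell under the low-count rule and entered no comparison, and had reads above the water level in the PS-MP libraries: 9, 11 and 11 reads in water replicates 1, 2 and 3 against 63, 30 and 706 reads in PS-MP replicates 1, 2 and 3. They include Slc17a7 of excitatory cortical neurons (193 reads in PS-MP replicate 3), Gad1 of inhibitory neurons (79) and Mobp of oligodendrocytes (114).

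Nerve within the liver is argued against. Over 11 transcripts of Schwann cells and peripheral neurons, reads were 14 to 29 in water and 66 in PS-MP replicate 3, against 808 to 910 and 7048 for the forebrain list. The excess over water of these peripheral transcripts was 0.723% of that of the forebrain list (upper 95% Poisson bound 1.01%), where nerve outside the brain would bring its own abundant transcripts. A candidate explanation that stays open is brain RNA or brain reads from 1 source shared by the PS-MP libraries: over the 9 brain-list genes with at most 4 reads in water together and at least 20 in PS-MP replicate 3, no departure from 1 ratio between the 3 PS-MP libraries was detected (simulated chi-square p = 0.163). Their level was 8.85% of that of replicate 3 in replicate 1 and 2.29% in replicate 2. Whether that would be tissue, RNA or reads from another library was not tested. An effect of PS-MP exposure cannot be told apart from it by group, because all 3 PS-MP libraries lay above water: the lowest had a summed 3.33 CPM of those genes, the highest 145, and water at most 0.295.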

How the results depend on the processing

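The pseudocounts, other scalings, robust fit and removal of libraries with brown fat transcripts were chosen after seeing the data, the other alternatives before. All 65 changed genes kept their direction in the 18 refits of scaling, pseudocount, low-count rule, model or libraries. For pseudocount, low-count rule and libraries this was fixed, as their groups do not overlap. With CPM of at least 1 in 3 libraries, 1 was untested. With median-of-ratios scaling, TMM scaling or the 20 most abundant genes left out, 56 changed, 23 higher and 33 lower. Between 61 and 72 changed with pseudocounts of 0.1 or 1, CPM of at least 1 in 3 libraries or robust empirical Bayes. With no low-count rule 0 genes changed (0 higher, 0 lower), with 26854 tested and 2064 at an unadjusted p under 0.05. Limma-voom on the recovered reads called 131 (65 higher, 66 lower). With water replicate 1 and PS-MP replicate 3, those with the most Ucp1 reads, left out together, 2 changed, 1 higher (Upp2) and 1 lower (Cdkn1a). With all 3 libraries that hold brown fat transcripts left out (water replicate 3 as well), limma-trend called 0 (0 higher, 0 lower), with 1037 genes at an unadjusted p under 0.05; the lone water library is then assumed to vary like the PS-MP libraries. An absolute log2 fold change of at least 1 left 25, and an adjusted p under 0.1 gave 135. Leaving out 1 library gave 0 to 36 changed genes, 0 to 21 higher and 0 to 16 lower, and 6 to 12 lists (12 without water replicate 2). Camera with an estimated correlation and fry each left 0 of 7 lists.

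No pairing of the libraries by replicate number was detected: deviations from the group means correlated at -0.036, 0.047 and -0.01 for equal numbers. With 3 libraries per group and no label for cage or day, a shared one is not excluded. With the replicate block 23 genes changed (10 higher, 13 lower). Not every library correlated best with its own number; the highest correlation was 0.065, of water replicate 1 with PS-MP replicate 3.

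Of the 7 lists past camera's threshold, the PER-phase, BMAL1-phase and fatty acid oxidation lists kept their call in all 18 refits and lost it with an estimated correlation; the others lost it in at least 1 refit. The median of the ribosomal protein list turned to 0.012 (adjusted p = 0.94; 4.24e-07 to 0.94 over its alternatives) with water replicate 1 and PS-MP replicate 3 left out, and to 0.004 with all 3 left out. With all 3 left out, the median of the sinusoidal endothelial list turned to 0.107 and that of oxidative phosphorylation to -0.072, both past the threshold; the cause was not tested. The planned DESeq2 fit was not run, and edgeR is used for no value here, because the files hold FPKM; an exploratory edgeR fit on the recovered reads called more genes than limma-voom, and its values are not reported.

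The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 65 genes (32 higher, 33 lower), 1 of 10 with as many, and the highest other split 0, with 341 to 795 genes at an unadjusted p under 0.05 in the others and 1737 in the real one. For lists the real split gave 7 and the highest other 14, and 8 of the 10 splits gave at least 7.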

Other observations

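The test of the clock genes below was chosen after their values had been seen, and so were the genes named here. Nampt, the rate-limiting enzyme of NAD salvage, was 1.42-fold higher (adjusted p = 0.0487 by limma) and Slc25a51, the mitochondrial NAD carrier, 1.37-fold (adjusted p = 0.0461). Id3 was 2.41-fold higher beside Id1 at 2.49-fold, both known targets of BMP signalling. Fpgs, which retains folate in cells, had a log2 fold change of -0.46. Acsl1, which activates long-chain fatty acids, had -0.50 and Elovl5 -0.62. All of these passed the threshold over all genes in the 6 libraries. Without water replicate 3 they lost their call, as did all 65 changed genes.

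Brown fat transcripts were found in water replicates 1 and 3 and in PS-MP replicate 3. Cidea had 47, 0 and 19 reads in water replicates 1, 2 and 3 and 0, 0 and 17 in PS-MP replicates 1, 2 and 3, and Adipoq 76, 3 and 13 against 0, 0 and 29. Lep, of white fat, had 0 reads in each of the 6 libraries. Retn of the white fat list had 14, 0 and 9 reads in water and 0, 0 and 6 in PS-MP. Acvr1c of that list had 17, 0 and 3 reads in water and 1, 0 and 10 in PS-MP. Whether white fat was present as well was not tested. Over the whole brown fat list, in which 3 of 12 genes are expressed at 1 FPKM or more in every water library, reads were 3391 to 6251 in water and 2208 to 2816 in PS-MP, of which Elovl3, which liver also expresses, gave 2842 to 4882 and 1986 to 2276. Over the white fat list, with 4 of 10 such genes, they were 68116 to 79049 and 67678 to 80818, of which Pck1, abundant in liver, gave 67311 to 78536 and 67186 to 80211. These sums are therefore no measure of fat tissue. The lists share 4 genes.

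The clock genes of opposite phases moved in opposite directions: 18 of the 20 tested genes had a positive sign if of the PER phase and a negative sign if of the BMAL1 phase. The signs do not tell a later from an earlier phase. Brain transcripts in the PS-MP libraries are argued against as the only source of the higher PER-phase genes. The excess over water in PS-MP replicates 1 and 2 was a median share of 0.559 of that in replicate 3 over the 14 PER-phase genes (quartiles 0.477 and 0.644), where Snap25 had a share of 0.0498. For Nr1d1 both excesses were negative. A brain contribution to part of the excess in replicate 3 is not excluded by this test, which did not cover the BMAL1-phase genes. A different hour of collection or feeding between the groups may account for the pattern and cannot be told apart from an effect of PS-MP on the liver clock, since the labels give no hour and both predict the same signs. The absolute median of the PER-phase list was 0.76 in the real split of the libraries and at most 0.52 in the other 9. For that list the order was largely fixed in advance and is no separate test. All its genes but Nr1d1 had every PS-MP value above every water value. The absolute median of the fatty acid oxidation list was 0.26 in the real split and at most 0.19 in the others.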
